A study of Mus musculus with 4 samples.

How the data were processed

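Endothelial cells were sorted from subcutaneous KPC tumours, and per the labels' protocols total RNA was made into libraries with a low-input stranded total RNA kit and sequenced as paired reads of 150 bases. Per the file headers the authors counted reads with featureCounts 2.0.1 on the GENCODE vM25 annotation of GRCm38, grouped by gene name, and the deposited table holds raw read counts for 55367 gene names. The recorded command has no paired-end option and no strand option, so each mate was counted on its own and reads from a gene and an antisense partner cannot be told apart. Among counts from 1 to 10, 66.3% to 74.8% were even in the 4 libraries. Per the submitters' processing notes, STAR 2.7.5b and DESeq2 1.28.1 were used. A second deposited table named as normalized held the same counts, cell by cell: 0 of 221468 cells differed, so it was used for this check only.

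The design, tests, gene lists and the rule for named genes were fixed before the data were examined. Genes were kept by filterByExpr at a minimum count of 10, which left 16945, and were scaled by TMM. Groups were compared with the quasi-likelihood test of edgeR 4.0.16 with robust dispersion in R 4.3.3, without covariates, with Benjamini-Hochberg adjusted p under 0.05. The 45 gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 on log2 CPM with a prior count of 2 where at least 5 members were tested, which left 44 lists, and again with an estimated correlation and with fry, which asks whether the members move one way on balance. Of 1116 list entries, 1113 were found, 26 of them through RefSeq synonyms of GRCm38.p6, since the lists used older names. This matching was added after the data were seen; with exact names 8 lists passed instead of 10, because the histone list could not be tested and the immediate early list no longer passed. Coordinates are those of the deposited table, GRCm38.

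Named genes were Cd93, Igfbp7, Mmrn2, Pecam1 and Ptprc; up to 10 genes per direction past the test with a mean of at least 5 CPM and no overlap between groups or, where under 5 passed, the 5 with the smallest p meeting the same limits; 3 members of each list past its test in the list's direction; and 1 member, the one with the smallest p, of each other list. Predicted genes with symbols starting Gm or ending Rik were not named by this rule, and 1 gene that the rule names is not reported here.

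The depth of 9364294 to 17813993 assigned reads per library and the 2 libraries per group limit the precision. Data were simulated for the 16945 tested genes from the means, dispersions and library sizes of this comparison. In them edgeR recovered 31 of 100 genes changed 2-fold and 71 of 100 changed 4-fold, with 10 false calls. DESeq2 1.42.0 recovered 35 and 71 with 14 false calls. Each gene was drawn on its own, with no shift shared across a library, although control IgG replicate 2 stood apart from the rest. The recovered shares therefore cannot stand for the power in these libraries. In a second simulation over the same genes, camera called all 3 lists shifted by a log2 change of 0.5 and 0 of the 31 lists without a shifted member. In the real data the estimated correlation, among the 10 lists that passed camera, ran from 0.036 (G1/S and DNA replication) to 0.72 (replication-dependent histones). Each grouping that put a control and an anti-CD93 library together still called 7 lists. The simulated 0 therefore cannot stand for the rate of false list calls in these libraries.

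Alternatives fixed in advance were other scalings, no count filter or a minimum count of 50, DESeq2, limma-voom, no robust dispersion, the replicate number as a block, each library left out in turn, and thresholds of 0.1 or a log2 fold change of at least 1. Halved counts, DESeq2 on the filtered genes, protein-coding genes only, removal of each library's trend with gene length and GC, and exact list names were chosen after the data were seen. GC and length came from GENCODE vM21 transcripts and the deposited table, and 98.9% of tested genes had both. A crossed replicate block was to be run only if same-numbered libraries deviated in opposite directions (correlation below -0.1), which was not met, so it is not reported.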

Results

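RNA was measured in 4 libraries of endothelial cells sorted from subcutaneous KPC tumours of C57BL/6 mice. KPC cells are a mouse pancreatic cancer line, and the sort kept cells that carried the endothelial protein CD31 and lacked the leukocyte protein CD45. The tumour-bearing mice had received either a control rat IgG or an antibody against CD93, a transmembrane receptor of endothelial cells, 48 hours before the cells were taken. Each group had 2 libraries, and the labels do not say whether these came from separate mice, so p-values measure only the spread between these libraries. The reads assigned to genes numbered 12264231 and 9364294 in control IgG replicates 1 and 2, and 17813993 and 13808077 in anti-CD93 replicates 1 and 2. Gene values are CPM (reads per 1e6 reads assigned to the tested genes, after TMM scaling) as mean ± SD (n = 2 per group), and log2 fold changes are anti-CD93 against control IgG. Unless another setting is named, results come from 1 fit of all 4 libraries, with a minimum count of 10 and the group as its only term.

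1 control library differed from the rest. Control IgG replicate 2 had the fewest reads but the most detected genes, 27718 against 23796 in control IgG replicate 1, 25430 in anti-CD93 replicate 1 and 24182 in anti-CD93 replicate 2. Mitochondrial ribosomal RNA made up 6.20% of its reads, against 11% in the other control library and 11.8% and 11.1% in the anti-CD93 libraries. Olfactory and vomeronasal receptor genes, which are normally read in sensory neurons, together took 359.6 CPM of all assigned reads in this library and 56.6, 52 and 54.6 CPM in control IgG replicate 1 and anti-CD93 replicates 1 and 2. Across genes, log2 CPM correlated between libraries at r = 0.977 to 0.983 where control IgG replicate 2 was not involved and at 0.945 to 0.947 where it was; genes are not independent replicates.

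**Figure D1:**
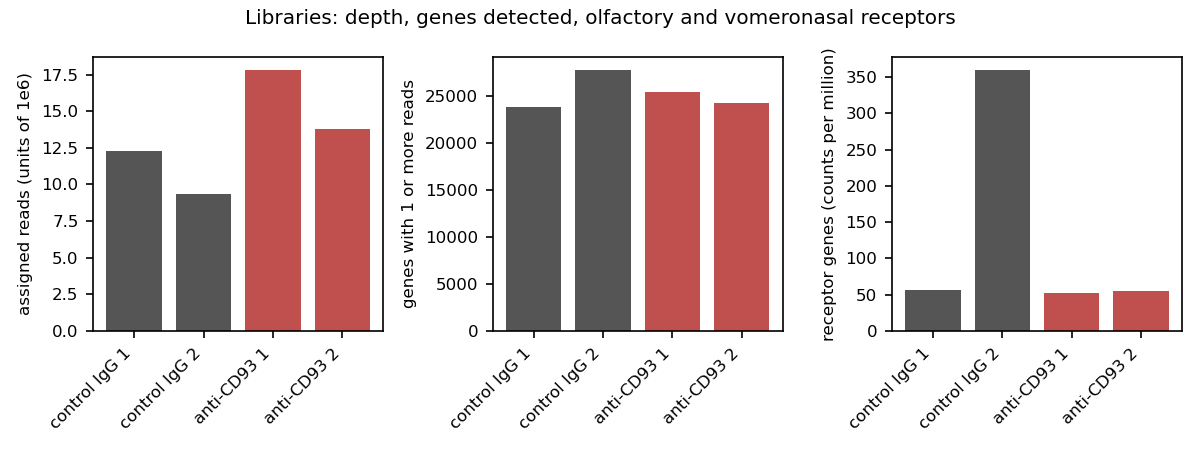
Bars give, for each of the 4 libraries, the number of assigned reads in units of 1e6, the number of genes with at least 1 read, and the summed CPM of olfactory and vomeronasal receptor genes (grey, control IgG; red, anti-CD93). Control IgG replicate 2 had the fewest reads, the most detected genes and 359.6 CPM of receptor reads.

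The series asked how antibody against CD93 changed expression in tumour endothelial cells. The target gene Cd93 (chromosome 2, 148436640 to 148443563, GRCm38) was at 1644 ± 162 CPM with control IgG and 1615 ± 143 CPM with anti-CD93 (log2 fold change -0.026, SE 0.18), a difference smaller than its standard error (SE). Igfbp7 (chromosome 5, 77349240 to 77408041), which encodes a secreted ligand of CD93, was at 2072 ± 112 CPM with control IgG and 1786 ± 62.2 CPM with anti-CD93 (log2 fold change -0.21, SE 0.17). Mmrn2 (chromosome 14, 34375465 to 34404287), which encodes multimerin-2, a matrix ligand of CD93, was at 891 ± 263 CPM with control IgG and 625 ± 16.2 CPM with anti-CD93 (log2 fold change -0.51, SE 0.22). The Mmrn2 value was -0.18 (adjusted p = 0.688 by edgeR) without control IgG replicate 2 and -0.78 (adjusted p = 4.82e-04 by edgeR) without control IgG replicate 1. With all 4 libraries the adjusted p values of these 3 genes were 0.976, 0.812 and 0.812 by edgeR. Of the sort markers, Pecam1 (chromosome 11, 106654217 to 106750628), which encodes CD31, was at 1779 ± 132 CPM with control IgG and 1662 ± 1.71 CPM with anti-CD93, and Ptprc (chromosome 1, 138062861 to 138175708), which encodes CD45, was at 3.54 ± 1.66 CPM with control IgG and 3.70 ± 1.95 CPM with anti-CD93. Their adjusted p values were 0.897 and 0.974.

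No single gene passed the test between the groups. Of 16945 genes tested with edgeR's quasi-likelihood test, 0 had an adjusted p under 0.05, and the smallest adjusted p was 0.812. At an unadjusted p under 0.05 there were 761 genes, 337 higher and 424 lower with anti-CD93, or 4.49% of those tested. Without any effect, a share of about 0.05 would pass. With 1 library left out this count ran from 160 without anti-CD93 replicate 1 to 6683 without control IgG replicate 1. DESeq2, run on all 33419 genes with reads, called 5 genes. Bnip3 and Aldh1a3 were higher, and Snord15a, Rnu3a and Gm10722 lower. Gm10722 falls outside the naming rule and was picked after its value was seen. Its log2 fold change was -23.8 (SE 4.79), against -1.26 to 1.44 for the others, so its size is no reliable estimate. On the 16945 genes DESeq2 called 4, the same without Gm10722, in a fit added after the data were seen. Limma-voom called 0, while edgeR with no count filter called 48. In 39.8% of the tested genes both anti-CD93 libraries lay on the same side of both control libraries. Without any effect, 33.3% is the average over the possible splits of the 4 libraries. Genes move together and the share was not computed for the other splits, so 39.8% is no evidence of an excess. The count depended on which libraries entered: without control IgG replicate 1, when control IgG replicate 2 alone stood for its group, edgeR called 4549 genes, and without control IgG replicate 2 it called 13. It called 0 without anti-CD93 replicate 1 and 1, Xist, without anti-CD93 replicate 2, a gene picked after its value was seen.

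The genes with the smallest p and no overlap between the groups are given with their values, none of them past the test (adjusted p = 0.812 by edgeR for each). On the higher side, Bnip3 (chromosome 7, 138890836 to 138909519), a mitochondrial mitophagy receptor and hypoxia target, was at 15.4 ± 0.726 CPM with control IgG and 39.6 ± 1.80 CPM with anti-CD93 (log2 fold change 1.36, SE 0.21). Aldh1a3 (chromosome 7, 66390890 to 66427517), which makes retinoic acid, was at 18.7 ± 4.56 CPM with control IgG and 50.1 ± 14.4 CPM with anti-CD93 (log2 fold change 1.43, SE 0.28). Adgrl3 (chromosome 5, 81020138 to 81825133), an adhesion receptor, was at 12.9 ± 4.15 against 30.5 ± 1.88 CPM in control IgG and anti-CD93. In the same order, Rnf128 (chromosome X, 139563316 to 139673145), a ubiquitin ligase, was at 9.64 ± 2.28 against 23.3 ± 4.45 CPM and Plekha2 (chromosome 8, 25039144 to 25102376) was at 10.8 ± 1.08 against 22.7 ± 1.11 CPM. On the lower side, the small nucleolar RNAs Rnu3a (chromosome 10, 40258467 to 40258680) and Snord15a (chromosome 7, 99482785 to 99482932) were at 165 ± 3.38 against 79.9 ± 12.2 CPM and 244 ± 80.7 against 101 ± 0.526 CPM. The histone gene H3c6 (chromosome 13, 23561534 to 23562369) was at 32.9 ± 13.8 against 13.3 ± 1.69 CPM, Lzts1 (chromosome 8, 69132669 to 69184225) at 13.2 ± 3.57 against 5.34 ± 0.674 CPM and the serpin gene Serpina3n (chromosome 12, 104406729 to 104414329) at 20.1 ± 3.11 against 8.35 ± 3.19 CPM. H3c6 has near-identical copies, so its count is uncertain. Of the 13 genes that edgeR called without control IgG replicate 2, 10 were higher and 3 lower with anti-CD93. They held Bnip3, Snord15a and Rnu3a, with log2 fold changes of 1.31, -0.90 and -1.07. In that fit control IgG replicate 1 alone stood for its group, so the spread came from the anti-CD93 libraries only. These genes were picked for small p in the same libraries, so their calls are no separate support.

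**Figure D2:**
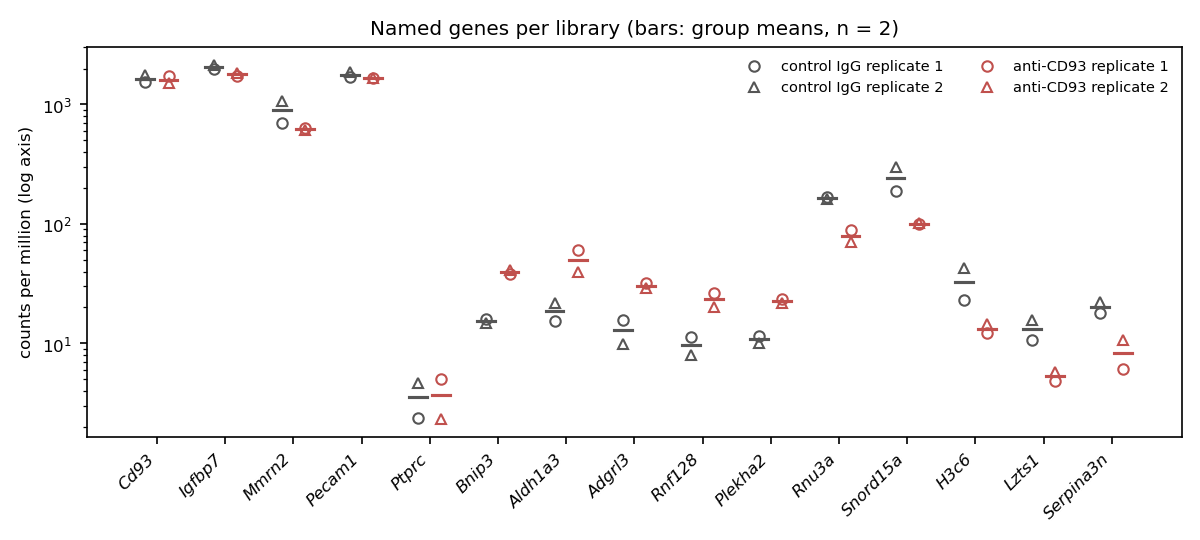
Points give the CPM (log axis) of each of the 4 libraries for the target, ligand and sort genes and for the leading genes of each direction (grey, control IgG; red, anti-CD93; circles, replicate 1; triangles, replicate 2), and bars the group means (n = 2). Cd93 lay at 1644 and 1615 CPM on average, and Bnip3 at 15.4 and 39.6 CPM.

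As groups, 10 of the 44 tested gene lists passed the set test (limma camera with a preset correlation), 3 upward and 7 downward. None of them passed with a correlation estimated from the libraries (adjusted p = 0.864 for each of the 10) or by limma's fry (adjusted p = 0.742 for each). The smallest unadjusted p of the 44 lists, for G1/S and DNA replication, was 0.086 with an estimated correlation and 0.047 by fry. Neither test was tried on the simulated lists, so its power with 2 libraries per group is unknown. These failures therefore cannot show that the lists did not change. Over all genes tested, 0 list members passed, and 6 passed when adjusted over the list alone. Hypoxia response genes, targets of the hypoxia-inducible factors, rose as a list. In it 25 of its 29 tested members lay higher and 4 lower, with a median log2 change of 0.31 (adjusted p = 2.77e-04 by camera, and adjusted p = 0.864 with an estimated correlation). Bnip3 of this list passed when adjusted over the list alone (adjusted p = 0.00486 by edgeR). The adenylate kinase gene Ak4 was at 7.18 ± 0.462 against 14.2 ± 0.311 CPM and the oxygen sensor gene Egln3 at 47.1 ± 9.0 against 78.8 ± 6.43 CPM. Interferon-alpha response genes fell as a list, with 31 of 34 members lower and a median of -0.34 (adjusted p = 1.30e-04 by camera, and adjusted p = 0.864 with an estimated correlation). Ifit1 was at 21.3 ± 2.49 against 11.4 ± 1.04 CPM, the nucleic acid sensor gene Zbp1 at 31.3 ± 2.24 against 18.4 ± 1.01 CPM and Dhx58 at 14.6 ± 2.07 against 7.37 ± 1.08 CPM.

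Genes of G1/S and DNA replication fell, with 27 of 32 members lower and a median of -0.25 (adjusted p = 5.35e-04 by camera, and adjusted p = 0.864 with an estimated correlation). The replication helicase genes Cdc45 and Mcm5 were at 12.2 ± 3.18 against 5.22 ± 1.55 CPM and 40.0 ± 11 against 24 ± 2.89 CPM, and Chaf1a was at 27.9 ± 9.0 against 16.3 ± 0.368 CPM. Replication-dependent histone genes fell, with 19 of 20 members lower and a median of -0.90 (adjusted p = 4.63e-06 by camera, and adjusted p = 0.864 with an estimated correlation). H3c1 was at 9.17 ± 5.35 against 3.52 ± 0.982 CPM, H1f4 at 200.3 ± 90.6 against 111 ± 13.2 CPM and H1f2 at 226 ± 90.3 against 137 ± 12.6 CPM. Histone copies can share reads. The summed level of the list was 569.6 and 1052 CPM in control IgG replicates 1 and 2 and 432 and 533 CPM in anti-CD93 replicates 1 and 2. The hypoxia, interferon-alpha, G1/S and histone lists passed camera without each library in turn, but the G1/S list did not pass with no count filter (adjusted p = 0.103). Without control IgG replicate 2 the medians were 0.16 (adjusted p = 0.00509) for hypoxia, -0.15 (adjusted p = 0.0361) for interferon-alpha and -0.27 (adjusted p = 0.0255) for histones. Without control IgG replicate 1 the interferon-alpha median was -0.55 (adjusted p = 1.76e-04).

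The other 6 lists lost their call without at least 1 of the libraries. Genes of interferon-gamma and antigen presentation fell (32 of 35 lower, median -0.37, adjusted p = 7.12e-04 by camera, and adjusted p = 0.864 with an estimated correlation). H2-T22 was at 75.9 ± 5.65 against 54.5 ± 3.48 CPM, Psmb10 at 25.6 ± 15.9 against 13.3 ± 0.300 CPM and Irf8 at 62.7 ± 5.90 against 47.6 ± 1.41 CPM. H2-T22 belongs to the near-identical class I family, so its count is uncertain. Without control IgG replicate 2 the median was -0.045 (adjusted p = 0.957), and without control IgG replicate 1 it was -0.58 (adjusted p = 3.24e-07). Pan-endothelial identity genes fell (28 of 34 lower, median -0.20, adjusted p = 0.00440 by camera, and adjusted p = 0.864 with an estimated correlation). The tight junction gene Cldn5 was at 157 ± 1.51 against 105 ± 11.8 CPM, the nitric oxide synthase gene Nos3 at 212 ± 35.7 against 139.6 ± 21.5 CPM and Egfl7 at 729 ± 178 against 516 ± 10.3 CPM. The median was -0.080 (adjusted p = 0.137) without control IgG replicate 2, -0.15 (adjusted p = 0.122) without anti-CD93 replicate 1 and -0.32 (adjusted p = 0.00421) without control IgG replicate 1.

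Nuclear oxidative phosphorylation genes fell (30 of 38 lower, median -0.18, adjusted p = 0.0263 by camera, and adjusted p = 0.864 with an estimated correlation). Ndufa8 was at 51.4 ± 19.8 against 31.4 ± 2.54 CPM, Cox5b at 97 ± 35.4 against 65.1 ± 6.68 CPM and Ndufs3 at 21.9 ± 6.54 against 15 ± 1.30 CPM. The list's median was -0.0060 (adjusted p = 0.802) without control IgG replicate 2, -0.20 (adjusted p = 0.0529) without anti-CD93 replicate 1 and -0.17 (adjusted p = 0.156) without anti-CD93 replicate 2. Mitochondrially encoded genes rose (11 of 13 higher, median 0.41, adjusted p = 9.33e-04 by camera, and adjusted p = 0.864 with an estimated correlation). The complex I genes mt-Nd6, mt-Nd5 and mt-Nd4 were at 236 ± 25.3 against 371 ± 67.7 CPM, 561 ± 104 against 805 ± 102 CPM and 308 ± 69.3 against 443 ± 43.4 CPM. Counting ignored strand, and mt-Nd6 lies on the strand opposite to most of its neighbours. Their list median was 0.31 (adjusted p = 0.0529) without control IgG replicate 2, 0.21 (adjusted p = 0.0689) without anti-CD93 replicate 1 and 0.67 (adjusted p = 0.0133) without control IgG replicate 1.

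Immediate early genes, which tissue digestion raises, fell (24 of 30 lower, median -0.12, adjusted p = 0.0482 by camera, and adjusted p = 0.864 with an estimated correlation). Socs3 was at 654 ± 267 against 377 ± 14.6 CPM, Nr4a1 at 296 ± 62.4 against 197 ± 29.3 CPM and Hspa1a at 745 ± 180.0 against 507 ± 54.9 CPM. This list did not pass in any of the 4 fits that left 1 library out. Its median was -0.25 (adjusted p = 0.0954) without control IgG replicate 1, -0.13 (adjusted p = 0.137) without control IgG replicate 2, -0.15 (adjusted p = 0.333) without anti-CD93 replicate 1 and -0.20 (adjusted p = 0.0615) without anti-CD93 replicate 2. Erythroid genes rose (9 of 10 higher, median 0.39, adjusted p = 0.00440 by camera, and adjusted p = 0.864 with an estimated correlation), some of them from near the floor. The globin gene Hbb-bt had 1 read in each control library and 52 and 29 reads in anti-CD93 replicates 1 and 2. Hba-a2 was at 1.98 ± 0.0795 against 5.74 ± 2.67 CPM, and globin copies share reads. The erythroid median was 0.0071 (adjusted p = 0.723) without control IgG replicate 1 and 1.01 (adjusted p = 2.09e-04) without control IgG replicate 2.

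Some single genes of these lists also rested on control IgG replicate 2. Without it the log2 fold change of 32 of the 72 named genes, inside these lists or outside them, moved by over 1.5 times. It became smaller or turned sign in 30. Among the histones it went for H3c1 from -1.38 to -0.62, H1f4 from -0.85 to -0.30, H1f2 from -0.72 to -0.25 and H3c6 from -1.30 to -0.80. Of the replication genes, Mcm5 went from -0.74 to -0.43 and Chaf1a went from -0.77 to -0.40. In the interferon-gamma list Psmb10 went from -0.94 to -0.11, and to -1.47 without control IgG replicate 1. The value went for Egfl7 from -0.50 to -0.22, for Ndufa8 from -0.71 to -0.25, for Cox5b from -0.57 to -0.14 and for Ndufs3 from -0.54 to -0.20, the last 2 reaching -0.90 and -0.82 without control IgG replicate 1. It also went for Socs3 from -0.79 to -0.31, Nr4a1 from -0.58 to -0.35, Hspa1a from -0.56 to -0.29, mt-Nd5 from 0.52 to 0.34 and mt-Nd4 from 0.52 to 0.31. Other named members of these lists moved by less without that library. They were Bnip3, Ak4, Egln3, Ifit1, Zbp1, Dhx58, Cdc45, Cldn5, Nos3, H2-T22, Irf8, mt-Nd6, Hbb-bt and Hba-a2.

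Other settings also ended some of these calls by camera. With each library's trend with gene length and GC removed, a setting chosen after the data were seen, the median was -0.066 (adjusted p = 0.0879) for pan-endothelial identity and -0.12 (adjusted p = 0.156) for oxidative phosphorylation. It was 0.089 (adjusted p = 0.986) for mitochondrially encoded genes and -0.019 (adjusted p = 0.735) for immediate early genes. With no count filter it was -0.15 (adjusted p = 0.417) for pan-endothelial identity, -0.31 (adjusted p = 0.103) for interferon-gamma, -0.13 (adjusted p = 0.554) for oxidative phosphorylation and -0.069 (adjusted p = 0.617) for immediate early genes. Among protein-coding genes only, also chosen after the data were seen, it was -0.15 (adjusted p = 0.0525) for oxidative phosphorylation and -0.086 (adjusted p = 0.0913) for immediate early genes.

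**Figure D3:**
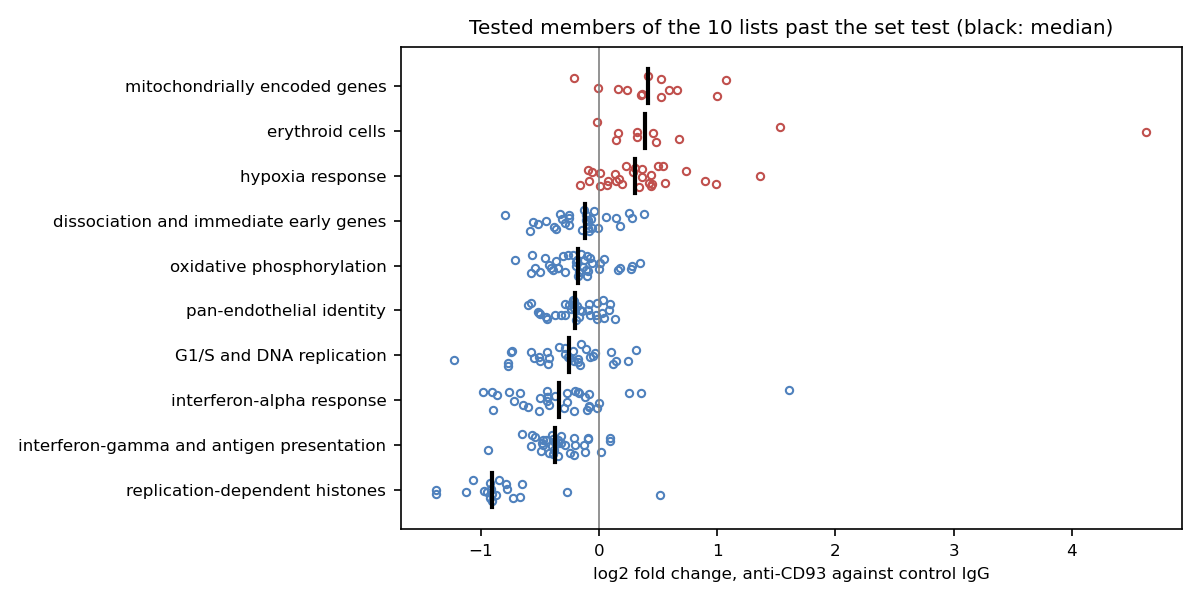
Points give the log2 fold change (anti-CD93 against control IgG, horizontal axis) of each tested member of the 10 lists past the set test, with vertical scatter only for legibility, and black bars the medians. Medians ran from -0.90 for replication-dependent histones to 0.41 for mitochondrially encoded genes, and single members spread on both sides of 0.

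The remaining vessel programmes did not pass the set test. For each list the median log2 change, the adjusted p by camera and the member with the smallest p follow, with control IgG first and anti-CD93 second. The CD93 axis had a median of -0.10 (adjusted p = 0.436), with Mmrn2 at 891 ± 263 against 625 ± 16.2 CPM. VEGF receptors and response had a median of 0.014 (adjusted p = 0.771), with Rcan1 at 83.4 ± 14.6 against 48.9 ± 4.78 CPM. Tip cell and sprouting genes had a median of -0.077 (adjusted p = 0.399), with Ramp3 at 32.1 ± 4.89 against 18.9 ± 4.65 CPM. The Notch pathway had a median of -0.18 (adjusted p = 0.399), with Jag1 at 133 ± 16 against 168 ± 15.3 CPM. Angiopoietin, Tie and FOXO1 targets had a median of 0.034 (adjusted p = 0.964), with Klf2 at 258 ± 14.3 against 158 ± 41.8 CPM. Endothelial junctions had a median of -0.025 (adjusted p = 0.984), with Cldn5 at 157 ± 1.51 against 105 ± 11.8 CPM. Basement membrane and matrix had a median of -0.21 (adjusted p = 0.0661), with Plod2 at 23.3 ± 9.44 against 43.8 ± 8.06 CPM. Integrins and focal adhesion had a median of -0.068 (adjusted p = 0.723), with Zyx at 185 ± 63 against 118 ± 4.72 CPM. Klf2 encodes a flow-induced transcription factor, Jag1 a Notch ligand and Rcan1 a calcineurin inhibitor induced by VEGF.

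The lists of inflammation and metabolism did not pass either. Leukocyte adhesion and chemokines had a median of -0.18 (adjusted p = 0.151), with Sele at 63 ± 16.8 against 33.7 ± 3.17 CPM. The NF-kB and TNF response had a median of -0.13 (adjusted p = 0.257), with Sele at 63 ± 16.8 against 33.7 ± 3.17 CPM. Immune regulation by endothelium had a median of -0.11 (adjusted p = 0.723), with Arg1 at 2.82 ± 0.407 against 7.49 ± 1.01 CPM. Glycolysis genes had a median of 0.091 (adjusted p = 0.487), with Hk2 at 91.3 ± 2.91 against 138 ± 4.38 CPM. Fatty acid handling had a median of 0.016 (adjusted p = 0.964), with Cd36 at 205 ± 48.3 against 348 ± 73.7 CPM. Cholesterol synthesis had a median of -0.055 (adjusted p = 0.399), with Mvd at 13.8 ± 5.45 against 7.11 ± 0.224 CPM. Sele encodes E-selectin, Hk2 a hexokinase and Cd36 a fatty acid transporter.

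Lists of growth control, clotting and RNA handling were also short of the threshold. G2/M and mitosis had a median of -0.033 (adjusted p = 0.275), with Cdc20 at 17.1 ± 4.25 against 10.4 ± 0.369 CPM. Targets of p53 and apoptosis genes had a median of 0.064 (adjusted p = 0.768), with Pmaip1 at 32.6 ± 0.0155 against 46.1 ± 7.84 CPM. Shear stress and quiescence had a median of -0.055 (adjusted p = 0.220), with Pi16 at 5.48 ± 0.129 against 1.54 ± 0.902 CPM. YAP and TEAD targets had a median of -0.069 (adjusted p = 0.826), with F3 at 32.1 ± 7.04 against 50.9 ± 4.70 CPM. TGF-beta and endothelial-mesenchymal genes had a median of -0.072 (adjusted p = 0.743), with Id2 at 21.1 ± 2.40 against 32.5 ± 1.84 CPM. Coagulation and fibrinolysis had a median of -0.044 (adjusted p = 0.822), with Procr at 66.4 ± 11.4 against 40.7 ± 0.504 CPM. Unfolded protein and ATF4 response had a median of 0.066 (adjusted p = 0.964), with Ppp1r15a at 305 ± 76 against 179 ± 1.13 CPM. Ribosomal proteins had a median of -0.14 (adjusted p = 0.0871), with Rpl19 at 364 ± 137 against 246 ± 9.85 CPM. Long nuclear RNAs had a median of 0.12 (adjusted p = 0.850), with Malat1 at 12936 ± 3013 against 18833 ± 2068 CPM. Immune regulation, VEGF response, fatty acid handling, unfolded protein response and endothelial junctions had a median, mean or test direction that differed in sign.

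Markers of vessel types and of other cells described the makeup of the sort. In the fit without other terms the vessel-type lists did not pass. Arterial endothelium had a median of -0.26 (adjusted p = 0.110), with Fbln5 at 92.5 ± 20.4 against 66 ± 3.92 CPM. Venous and postcapillary endothelium had a median of -0.19 (adjusted p = 0.0661), with Sele at 63 ± 16.8 against 33.7 ± 3.17 CPM. Capillary endothelium had a median of -0.053 (adjusted p = 0.822), with Cd36 at 205 ± 48.3 against 348 ± 73.7 CPM. Lymphatic endothelium had a median of -0.25 (adjusted p = 0.0661), with Tbx1 at 10.9 ± 2.75 against 6.17 ± 1.54 CPM.

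Epithelial and pancreatic tumour genes were abundant in every library, summing to 2118 and 2997 CPM in control IgG replicates 1 and 2 and to 3162 and 2595 CPM in anti-CD93 replicates 1 and 2. As a list they did not pass (median 0.18, adjusted p = 0.240 by camera), though 4 of its 17 tested members passed when adjusted over the list alone, all higher with anti-CD93. These were Onecut2 at 99.4 ± 24.7 against 192 ± 8.83 CPM, Muc1 at 41.6 ± 9.13 against 75.2 ± 4.58 CPM, Epcam at 22.6 ± 1.23 against 37.6 ± 4.99 CPM and Cdh1 at 213 ± 4.28 against 321 ± 43.4 CPM (adjusted p by edgeR 0.0335, 0.0335, 0.0452 and 0.0458), while none passed over all genes in the same fit. With no count filter Onecut2 did pass over all genes by edgeR, at a log2 fold change of 0.99. Without control IgG replicate 2, Muc1, Onecut2 and Ehf of this list were among the genes that edgeR called. All were higher with anti-CD93, with log2 fold changes of 1.10, 0.72 and 1.30. Control IgG replicate 1 then stood alone for its group, so that fit held no spread between controls. Ehf, Muc1, Epcam and Cdh1 fall outside the naming rule and were picked after their values were seen.

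The remaining cell-type lists did not pass in that fit. Macrophages and monocytes had a median of 0.11 (adjusted p = 0.0837), with Mrc1 at 12 ± 1.51 against 20.9 ± 4.65 CPM. Fibroblasts had a median of -0.21 (adjusted p = 0.110), with Pi16 at 5.48 ± 0.129 against 1.54 ± 0.902 CPM. Pericytes and smooth muscle had a median of -0.29 (adjusted p = 0.279), with Kcnj8 at 106 ± 1.57 against 73.9 ± 8.01 CPM. Neutrophils had a median of -0.38 (adjusted p = 0.110), with Il1r2 at 3.44 ± 1.64 against 1.51 ± 0.537 CPM. Platelets and megakaryocytes had a median of 0.29 (adjusted p = 0.487), with Plek at 11.7 ± 3.74 against 16 ± 2.03 CPM. Muscle, fat and skin had a median of 0.23 (adjusted p = 0.822), with Lor at 4.84 ± 3.61 against 2.44 ± 0.657 CPM. Lymphocyte markers had only 4 tested members, too few for the set test, and summed to 11.3 and 15.8 CPM in the control libraries and 8.59 and 6.76 CPM in the anti-CD93 libraries. Without control IgG replicate 2 the macrophage list passed with a median of 0.86 (adjusted p = 7.27e-07) by camera, and without control IgG replicate 1 its median was -0.26 (adjusted p = 0.400).

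Further lists passed camera with all 4 libraries under other settings. At a minimum count of 50 these were tumour epithelium with a median of 0.26 (adjusted p = 0.00854), macrophages and monocytes with 0.33 (adjusted p = 0.00909) and lymphatic endothelium with -0.31 (adjusted p = 0.0208). Venous and postcapillary endothelium had -0.18 (adjusted p = 0.0359) there, basement membrane and matrix -0.21 (adjusted p = 0.0362) and ribosomal proteins -0.15 (adjusted p = 0.0387). With the length and GC trend removed they were tumour epithelium with 0.30 (adjusted p = 0.00709), macrophages and monocytes with 0.22 (adjusted p = 0.0261) and glycolysis with 0.19 (adjusted p = 0.00860). G2/M and mitosis had -0.16 (adjusted p = 0.0171) in that setting, and leukocyte adhesion and chemokines -0.20 (adjusted p = 0.0302). With no count filter, macrophages and monocytes passed with 0.16 (adjusted p = 0.0214).

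Some other lists short of the threshold passed camera when 1 library was left out. These were, without control IgG replicate 1, basement membrane and matrix with a median of -0.35 (adjusted p = 0.00820) and ribosomal proteins with -0.30 (adjusted p = 1.76e-04). They were, without control IgG replicate 2, lymphatic endothelium with -0.35 (adjusted p = 0.0156) and platelets and megakaryocytes with 0.64 (adjusted p = 0.0255). Without anti-CD93 replicate 1 the neutrophil list passed with -0.82 (adjusted p = 0.0317). Without anti-CD93 replicate 2, basement membrane and matrix had -0.24 (adjusted p = 0.0498), venous and postcapillary endothelium -0.23 (adjusted p = 0.0198) and lymphatic endothelium -0.39 (adjusted p = 0.0374). In the same fit fibroblasts had -0.42 (adjusted p = 0.00332) and platelets and megakaryocytes 0.54 (adjusted p = 0.0198).

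Genes named outside the lists that passed moved too. The log2 fold change without control IgG replicate 2 went for Zyx from -0.65 to -0.25, Mvd from -0.95 to -0.49, Cdc20 from -0.72 to -0.45, Fbln5 from -0.49 to -0.24, Il1r2 from -1.18 to -0.61 and Ppp1r15a from -0.77 to -0.49. It also went for Jag1 from 0.34 to 0.22, Malat1 from 0.54 to 0.32, Plod2 from 0.90 to 0.54, Plek from 0.46 to 0.82, Rpl19 from -0.56 to -0.12 and Pecam1 from -0.098 to -0.021. The last 4, without control IgG replicate 1, were at 1.40, 0.16, -0.90 and -0.17, and Tbx1 went from -0.83 to -0.55. Without anti-CD93 replicate 1 the value went for Klf2 from -0.71 to -0.45 and for Hba-a2 from 1.53 to 0.96, the latter from the erythroid list. Without anti-CD93 replicate 2 it went for Pmaip1 from 0.50 to 0.31.

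Medians of the lists short of the threshold also shifted over the 4 fits that left 1 library out, here for lists that kept their sign. Tumour epithelium ran from 0.071 to 0.41, pericytes and smooth muscle from -0.50 to -0.0059, fibroblasts from -0.42 to -0.082, neutrophils from -1.07 to -0.22 and muscle, fat and skin from 0.029 to 0.24. Arterial endothelium ran from -0.40 to -0.052, venous and postcapillary endothelium from -0.32 to -0.072 and lymphatic endothelium from -0.39 to -0.11. The Notch pathway ran from -0.30 to -0.041, tip cell and sprouting from -0.12 to -0.0073, basement membrane and matrix from -0.35 to -0.039 and shear stress and quiescence from -0.15 to -0.047. Leukocyte adhesion and chemokines ran from -0.29 to -0.024, the NF-kB and TNF response from -0.29 to -0.029 and cholesterol synthesis from -0.20 to -0.0100. G2/M and mitosis ran from -0.14 to -0.013 and YAP and TEAD targets from -0.090 to -0.013.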

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

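Halved counts, DESeq2 on the filtered genes, protein-coding genes only, removal of the length and GC trend and exact list names were chosen after the data were seen. RLE, upper-quartile and total-count scaling kept the counts of genes (0), lists (10) and list members (6), as did halved counts; limma-voom and the fit without robust dispersion kept those of genes and list members, and thresholds of 0.1 or a log2 fold change of 1 also gave 0 genes. With no count filter, 48 genes passed (26 higher, 22 lower), with 67 list members and 6 lists, and a minimum count of 50 gave 16 lists; the cause was not tested. DESeq2 on all 33419 genes with reads, where tool and filter changed together, gave 5 genes (2 higher, 3 lower) and 26 list members. On the filtered genes it gave 4 (2 higher, 2 lower) and 22 list members. Lists numbered 0 with an estimated correlation and 0 by fry. Protein-coding genes only gave 8 lists and exact names 8. With the length and GC trend removed, 11 lists passed, 6 of them among the 10, and 15 list members. Deviations of same-numbered libraries correlated at -0.016. With 2 libraries per group and control IgG replicate 2 standing apart, this cannot decide whether the numbers pair the libraries. With the number as a block 14 genes passed (11 higher, 3 lower), with 39 list members and 11 lists, 9 of them among the 10. Bnip3, Aldh1a3, Adgrl3, Snord15a, Rnu3a, H3c6 and Onecut2 were among those genes, and the immediate early list lost its call, while the venous list (adjusted p = 0.0348) and the neutrophil list (adjusted p = 0.0348) passed by camera.

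Outside the fits that left a library out, 847 of 851 values of named genes that moved at all and 381 of 394 list medians kept their sign, and none that turned had passed a test. Log2 values that turned were, with no count filter, 0.025 for Cd93, 0.022 for endothelial junctions, 0.011 for G2/M and mitosis, 0.013 for TGF-beta and endothelial-mesenchymal genes, 0.0062 for coagulation and fibrinolysis, -0.86 for muscle, fat and skin; with protein-coding genes only, 0.0083 for Cd93, 0.0055 for endothelial junctions; and with the length and GC trend removed, 0.034 for Igfbp7, -0.32 for Ptprc, 0.041 for tip cell and sprouting, 0.050 for Notch pathway, 0.061 for endothelial junctions, 0.021 for immune regulation by endothelium, -0.0036 for fatty acid handling, 0.036 for shear stress and quiescence, 0.023 for capillary endothelium. The cause was not tested.

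Leaving out each library in turn, where a lone library is assumed to vary like the other group, moved the counts of genes most without control IgG replicate 1. Genes ran from 0 (without anti-CD93 replicate 1) to 4549 (without control IgG replicate 1). Higher genes ran from 0 to 2386, lower genes from 0 to 2163, list members from 2 to 447, and lists from 7 to 13. Log2 values that turned sign in at least 1 of these fits ran from -0.12 to 0.077 for Cd93, from -0.58 to 0.66 for Ptprc, from -1.61 to 0.083 for Lor, from -0.14 to 0.032 for CD93 axis. Others ran from -0.056 to 0.017 for VEGF receptors and response, from -0.10 to 0.060 for angiopoietin, Tie and FOXO1 targets, from -0.00013 to 0.029 for endothelial junctions, from -0.14 to 0.040 for integrins and focal adhesion. Further values ran from -0.20 to 0.084 for immune regulation by endothelium, from -0.053 to 0.18 for glycolysis, from -0.017 to 0.078 for fatty acid handling, from -0.044 to 0.16 for p53 targets and apoptosis. The next values ran from -0.16 to 0.057 for TGF-beta and endothelial-mesenchymal genes, from -0.017 to 0.027 for coagulation and fibrinolysis, from -0.064 to 0.038 for capillary endothelium, from -0.26 to 0.86 for macrophages and monocytes. Further values ran from -0.34 to 0.64 for platelets and megakaryocytes, from -0.051 to 0.12 for unfolded protein and ATF4 response, from -0.30 to 0.061 for ribosomal proteins, from -0.079 to 0.36 for long nuclear RNAs. Depth limits low genes, such as Hbb-bt with 1 read in each control library.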

Other observations

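Xist, the RNA that coats the inactive X chromosome, was at 841 and 538 CPM in control IgG replicates 1 and 2, at 35 CPM in anti-CD93 replicate 1 and at 858 CPM in anti-CD93 replicate 2. The Y-linked genes Ddx3y, Kdm5d and Eif2s3y had 0 reads in all 4 libraries and Uty had 1 read, in control IgG replicate 2. These genes were picked after their values were seen.

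The tests of sequencing depth, of tumour cell share and of control IgG replicate 2 as the sole source of list calls were chosen only after the results they bear on were seen. Control IgG replicate 2 stood apart from the other 3 libraries. Its olfactory and vomeronasal receptor reads were 6.35 times the highest of the others. They covered 679 detected receptor genes, against 75, 94 and 83 in control IgG replicate 1 and anti-CD93 replicates 1 and 2. Background reads spread over silent genes, such as from genomic DNA, may thus be part of the difference. In the same order, its protein-coding share was 89.3% against 84.0%, 83.1% and 84.0%. Its Malat1 share was 1.08% against 1.51%, 2.02% and 1.73%, so its composition differed beyond the receptor genes. Lower depth would give fewer detected genes, not more, and the deeper libraries already detected fewer before thinning. Thinned to its total, they detected at most 87.4% as many genes. Thinning can only lower that share, so this test added nothing. Gene length and GC explained 23.4% of the variance of its difference from the others, between the bounds set for and against a trend. The difference rose with GC (Spearman 0.53 over 16760 genes) and hardly varied with length (-0.036). How far a composition trend accounts for it stays open, and no biological explanation was tested.

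Epithelial genes that led the difference (Onecut2, Muc1, Epcam and Cdh1, picked for being high after their values were seen) had a median log2 change of 0.80, and the 4 most abundant epithelial transcripts (Krt8, Krt18 and Krt19 at 777 ± 226 against 784 ± 101 CPM, 511 ± 172 against 469 ± 55.4 CPM and 361 ± 123 against 353 ± 82.2 CPM, and Cdh1) one of -0.0092. More tumour cells in the anti-CD93 libraries would lift the keratins too, and the gap of 0.81 passed the bound of 2 SE with all 4 libraries. The SE of 0.24 was the median over the 4 abundant transcripts, not that of the gap. Since the leading genes were picked for being high, part of the gap was built in, so this test cannot decide. In fits added afterwards the gap, with the same limits, also passed 2 SE without control IgG replicate 1 (0.96, SE 0.12) or control IgG replicate 2 (0.40, SE 0.12). It did so without anti-CD93 replicate 1 (1.02, SE 0.37), but not without anti-CD93 replicate 2 (0.65, SE 0.37). Without control IgG replicate 2 the abundant transcripts themselves had a median of 0.36, and 3 of the 13 genes called in that fit were members of the epithelial list, all higher, so a larger share of tumour cells despite the CD31 gate could not be excluded. Removing the length and GC trend kept 101% of the leading genes' change, which argues against that trend, while an effect of the antibody stays open and untested.

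Of the 10 lists past the set test, 5 stayed past it in the same direction without control IgG replicate 2 and 6 with the length and GC trend removed, neither number deciding; only 60.0% of the tested histone members had a GC value. The 3 splits of the 4 libraries are too few for a share under 0.05: 1 of the 3, the real one, gave as many lists, with 10 against a highest other of 7. An effect of the antibody on these lists stays open and untested.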
